A study of Mus musculus with 12 samples.

How the data were processed

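RNA was measured on 12 Affymetrix arrays from MLE12 cells, a mouse distal lung epithelial line transformed with the SV40 large T antigen. Cells at 60% confluency were infected for 12 hours with lentivirus carrying a pLKO.1 shRNA construct and collected after 65 hours of subculture, per the labels' protocols. The virus was made in HEK-293T cells, a human embryonic kidney line. From each culture 100 ng of total RNA was copied from a poly(T) primer, amplified and labelled with biotin. The labels give 4 groups of 3 arrays, described as biological replicates: shRNA against the RNA named NANCI, a scrambled shRNA run with it, shRNA against the RNA named LL34, and a scrambled shRNA run with that one. They do not say whether replicates came from separate infections, so p-values measure the spread between these arrays.

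The deposited values are log2 signals per probe set, 1 value per array. The tools oligo, RMA (background correction, quantile normalization and a summary per probe set) and limma are named per the submitters' processing notes. Their versions, their order and the annotation version are not given in the sources used here. The values looked as if each set of 6 arrays had been normalized on its own. Array medians ran from 6.84 to 6.88 in the NANCI set and from 6.54 to 6.61 in the LL34 set. No probe set had exactly equal values on 2 arrays of different sets. Within the LL34 set, up to 1681 probe sets were exactly equal on a pair of arrays, against at most 27 within the NANCI set. All 3 arrays of a group had 1 value for 464 probe sets in the LL34 shRNA group and for 212 in the LL34 scrambled group, against 0 and 1 in the NANCI groups. A group SD of 0 in the LL34 set therefore says nothing of the spread between cultures. The tests drew their spread from all 4 groups, tied values included, so errors and p-values of such probe sets may be too small. Scale and direction of the values are log2 signals that rise with RNA, and no centring on a gene was seen.

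Probe sets were named through the platform's annotation table. Of 41345 probe sets, 23521 had 1 gene symbol, 1814 had several and 16010 had none. Only those with 1 symbol were named, and 23328 of them had an Entrez number in a mouse gene table of assembly GRCm38.p6. They covered 22180 genes, of which 1082 had more than 1 probe set. The brightest probe set, by its mean over all arrays, stood for such a gene. The gene table lists Nanci as a synonym of Sfta3-ps and places that gene beside Nkx2-1. No entry of the tables used here carries the name LL34, so the RNA targeted by that shRNA was not analysed here.

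The tests were limma 3.58.1 in R 4.3.3 on the deposited log2 values of all 12 arrays, with 4 group means and 8 residual degrees of freedom, and empirical Bayes moderation (2.84 prior degrees of freedom). The package data.table, version 1.17.8, read and wrote values. The comparisons were each shRNA group against the scrambled group of its own set, the difference between those 2 changes, and the scrambled group of the LL34 set against that of the NANCI set. P-values were adjusted by the Benjamini-Hochberg method over the 41345 probe sets of each comparison, with a threshold of 0.05. Changes are on the log2 scale, shRNA minus scrambled, with the standard error (SE) of the fit. The sets had no common control arrays, and no array scan date or batch was given in the sources used here. For arrays, their number limits the precision.

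The comparisons, the list tests of each knockdown, the alternatives, the gene lists and the rule for named genes were chosen before the data were examined. The list tests of the difference, of the scrambled groups and of the shRNA groups, with their alternatives, were added after the data were seen. The rule named Nkx2-1, the targeted RNA where a table paired it with a probe set, and the neighbouring genes. It also named the 10 highest and 10 lowest changes per knockdown among called probe sets with 1 gene, with all 3 shRNA arrays on 1 side of all 3 scrambled arrays and without placeholder names. In each list past the threshold, and in 3 lists regardless (alveolar type 2 and surfactant, lung endoderm transcription factors, retinoic acid signalling), it named up to 4 members, those with the smallest p. For the difference it named 5 genes in each direction, without the condition on single arrays, and for the scrambled groups 3.

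There were 28 gene lists of 767 entries, of which 708 matched a measured gene. They covered alveolar type 1, alveolar type 2 and surfactant, airway secretory, ciliated, basal and squamous, mesenchymal and matrix, endothelial and leukocyte genes. Others held lung endoderm transcription factors, targets or parts of the retinoic acid, Wnt, BMP and TGF-beta, Hedgehog, FGF and ERK, and Notch pathways, and epithelial junction and keratin genes. The rest held proliferation, interferon response, NF-kB inflammatory, p53, unfolded protein response and ATF4, cholesterol synthesis, fatty acid and phospholipid synthesis, hypoxia and glycolysis, oxidative stress NRF2, mitochondrial oxidative phosphorylation, cytosolic ribosomal protein, and immediate early and heat shock handling stress genes. Each list was tested against all other genes with limma's camera at a preset correlation of 0.01, adjusted over the 28 lists of a comparison, and again with the correlation estimated from the arrays. The preset takes genes of a list as nearly independent, so the p with an estimated correlation is given beside each call it ends.

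The alternatives were a fit of only the 6 arrays of a comparison, the replicate number as a block within each set, quantile normalization over all 12 arrays, arrays centred on their medians, only probe sets at or above the median level, only probe sets naming 1 gene, an intensity trend with robust variance, array weights, a change of at least 1 on the log2 scale, a threshold of 0.01, all 6 scrambled arrays as 1 control group, and each array left out in turn. For lists, fry and the mean of a gene's probe sets were also run. Fry asks whether a list's genes move, on balance, one way and does not compare them with other genes. Leaving out both deviating scrambled arrays (NANCI_control replicate 2 and LL34_control replicate 3) was added after the data were seen. Each array's name here is its group and the replicate number of its label.

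The method was tested on simulated arrays of 41345 probe sets with 50 probe sets changed per size. For the NANCI comparison it recovered 6%, 70%, 86% and 98% of changes of 0.25, 0.5, 1 and 2 on the log2 scale. For the LL34 comparison the shares were 4%, 68%, 90% and 98%. For the difference they were 0%, 30%, 76% and 96%, and for the scrambled groups 8%, 70%, 92% and 100%. False calls numbered 9, 9, 4 and 7 in the same order of comparisons. With so few changed probe sets the Benjamini-Hochberg cut-off was stricter than in the real comparisons. Each probe set also had 1 spread for all simulated arrays. These shares therefore do not give the share of real changes found. A list shifted by 0.5 was recovered in 20 of 20 simulations of the NANCI comparison on 22180 genes, with 1 false list call. Simulated genes were drawn independently of each other, so this does not measure false calls for lists whose genes move together. In the real arrays the estimated correlation was 0.524 for the cholesterol list. Regrouped real arrays with 0 called probe sets gave up to 8 called lists for NANCI and 11 for LL34.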

Results

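RNA levels were compared on 12 arrays of MLE12 lung epithelial cells, 3 per group, after lentiviral shRNA against the long noncoding RNAs NANCI or LL34. Each knockdown had its own 3 arrays of cells given a scrambled shRNA. Each array gave log2 signals for 41345 probe sets. Array medians ran from 6.84 to 6.88 in the NANCI set of 6 arrays and from 6.54 to 6.61 in the LL34 set, so levels were compared mainly within a set. Replicates of a group correlated at 0.986 or higher. The lowest mean correlations with the own group, 0.988 and 0.992, belonged to LL34_control replicates 3 and 1. The comparisons ask which genes changed in cells given the shRNA against each noncoding RNA, Nkx2-1 and other lung epithelial genes among them.

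Cells given the NANCI shRNA had less of the targeted RNA and less Nkx2-1 RNA. Sfta3-ps, the long noncoding RNA gene that the gene table lists with the synonym Nanci, fell by 2.91 on the log2 scale (SE 0.121, limma adjusted p = 1.72e-07). Its probe set, 17281291, went from 11.90 ± 0.133 to 8.98 ± 0.218 (SD, 3 arrays each), which left 13.3% of the scrambled level. Nkx2-1, the homeodomain transcription factor that the lung epithelium needs for its identity and that lies beside Sfta3-ps, fell by 1.00 (SE 0.0745, limma adjusted p = 4.95e-06) to 50.1%. Nkx2-9, a homeodomain gene nearby, rose by 0.75 (SE 0.116, limma adjusted p = 0.000742). Of the other neighbours, Pax9, a paired-box transcription factor, measured −0.20 (adjusted p = 0.264) and Mbip measured −0.08 (adjusted p = 0.612). Without NANCI_control replicate 1, Pax9 measured −0.33 with an adjusted p of 0.0299.

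Sfta3-ps and Pax9 changed in cells given the LL34 shRNA. Sfta3-ps fell by 0.67 (SE 0.121, limma adjusted p = 0.00284), to 62.6% of its scrambled level, and Pax9 rose by 0.48 (SE 0.107, adjusted p = 0.0103). The Pax9 call was lost with quantile normalization over all arrays (adjusted p = 0.0704) and against all 6 scrambled arrays as 1 control group (0.21, adjusted p = 0.372). Nkx2-1 fell by 0.27 (SE 0.0745, adjusted p = 0.0327). That call was lost when any 1 of LL34_shRNA replicates 1, 2 and 3 or LL34_control replicates 1 and 2 was left out, with adjusted p from 0.0862 to 0.119, in a fit of the 6 arrays alone (0.1) and with the replicate number as a block (0.0664). Against all 6 scrambled arrays Nkx2-1 measured −0.50 (adjusted p = 0.0413). Nkx2-9 measured −0.09 (adjusted p = 0.702) and Mbip 0.05 (adjusted p = 0.763).

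**Figure D1:**
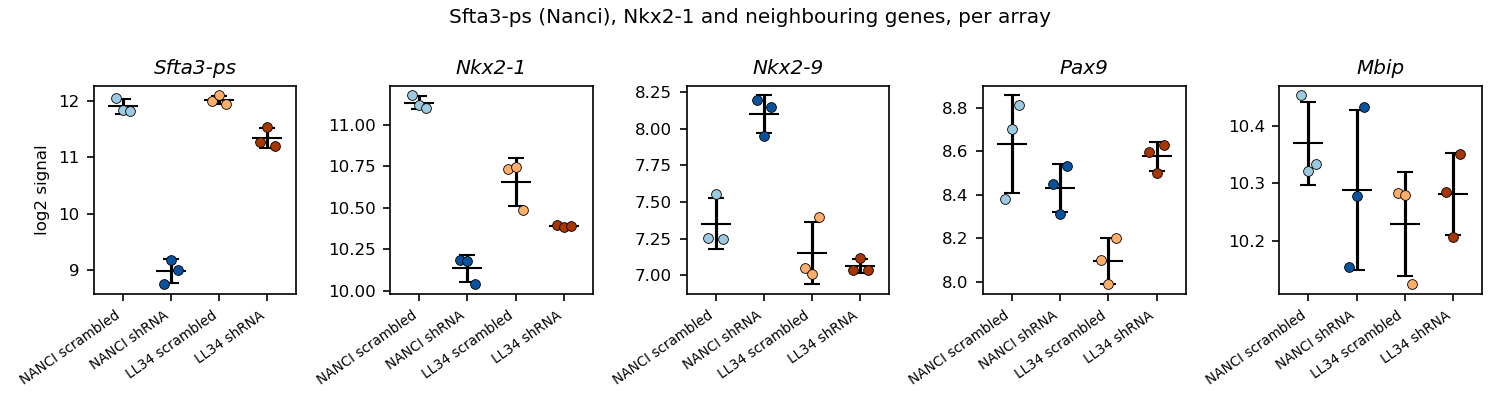
Log2 signal of Sfta3-ps, Nkx2-1, Nkx2-9, Pax9 and Mbip on each of the 12 arrays, with points for arrays and bars for the group mean and SD (3 arrays), each panel on its own scale. Sfta3-ps stood at 8.98 in the NANCI shRNA group against 11.90 in its scrambled group, and Nkx2-1 at 10.13 against 11.13.

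After NANCI knockdown, 8228 of 41345 probe sets passed the threshold, 4258 higher and 3970 lower, and 622 of them changed by at least 1 on the log2 scale. They held 5938 of 22180 named genes, of which 2919 rose and 3019 fell. Hspa1b, an inducible HSP70 chaperone, rose most (2.86, SE 0.158), followed by Atg9b, an autophagy lipid scramblase (2.19, SE 0.118), Slc4a11, a membrane transporter (2.07, SE 0.0917), and Lpin1, a phosphatidate phosphatase (1.96, SE 0.0939). Rgs16, a regulator of G-protein signalling, Nrn1, Pitpnc1, the histone gene H4c14, the class I gene H2-Q10 and Tbc1d8 rose by 1.93, 1.87, 1.85, 1.85, 1.76 and 1.76. Genes that fell most were B4galnt2, a glycosyltransferase (−2.99, SE 0.129), Sfta3-ps itself, Aqp1, a water channel (−2.83, SE 0.0891), Sprr1a, a cornified envelope protein (−2.67, SE 0.146), and Cox6a2, a subunit of cytochrome c oxidase (−2.55, SE 0.0985). Next came Aldh1l2, a mitochondrial folate enzyme (−2.50), Slc7a11, the cystine and glutamate exchanger (−2.39), the receptor gene Adgrd1 (−2.30), Pdia5, a protein disulfide isomerase (−2.30), and Vldlr, a lipoprotein receptor (−2.25). By the rule that chose these 20 genes, all shRNA arrays lay on 1 side of all scrambled arrays, as they did in 33% of all probe sets. Their limma adjusted p-values were at most 0.000133. The second probe set of H2-Q10 measured −0.02 (adjusted p = 0.943), and that of Slc7a11 −0.94 (adjusted p = 7.66e-05).

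Targets of p53, the stress-activated tumour suppressor, rose together after NANCI knockdown: 22 of 26 measured members rose and 2 fell, also when adjusted over the list alone (median 0.72, camera adjusted p = 7.8e-14). The call was lost with adjusted p = 0.0872 with an estimated correlation. Zmat3, an RNA-binding p53 target, rose by 1.72, Mdm2, the ligase that degrades p53, by 1.38, the kinase gene Plk2 by 1.33 and the apoptosis effector Perp by 1.04. Targets of NRF2, the oxidative stress regulator, rose in 18 of 22 cases with 1 fall, the same counts as when adjusted over the list alone (median 0.52, adjusted p = 4.29e-09; adjusted p = 0.0798 with an estimated correlation). Hmox1, heme oxygenase, rose by 1.48, Osgin1 by 1.32 and Gclm, a glutathione synthesis subunit, by 1.17. The member that fell was Slc7a11, also a target of ATF4. Oxidative phosphorylation genes rose in 17 of 31 cases and fell in 3, likewise when adjusted over the list alone (median 0.29, adjusted p = 5.25e-05; adjusted p = 0.292 with an estimated correlation). Ndufs1, Ndufs3, Sdhb and Uqcrfs1, subunits of respiratory complexes, rose by 0.76, 0.75, 0.85 and 0.96.

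Genes of handling stress (immediate early and heat shock) rose in 12 of 25 cases and fell in 4, or 14 and 6 when adjusted over the list alone (median 0.31, adjusted p = 0.00135; adjusted p = 0.212 with an estimated correlation). Beside Hspa1b, the chaperone genes Dnajb1 and Hspd1 rose by 1.08 and 0.76, while Klf4, an immediate early transcription factor, fell by 0.82. NF-kB inflammatory genes rose in 9 of 28 cases with 1 fall, or 9 and 2 when adjusted over the list alone (median 0.09, adjusted p = 0.0243; adjusted p = 0.212 with an estimated correlation). The chemokine gene Ccl2 rose by 1.51, the NF-kB inhibitor gene Tnfaip3 by 1.27 and the prostaglandin synthase gene Ptgs2 by 0.86, and the chemokine gene Ccl5 fell by 0.90. Without NANCI_control replicate 3 the NF-kB list had a median of 0.059 (adjusted p = 0.0307), and among probe sets at or above the median level its call was lost (0.0641). Cytosolic ribosomal protein genes rose in 7 of 32 cases and fell in 2, or 10 and 2 when adjusted over the list alone (median 0.10, adjusted p = 0.0326; adjusted p = 0.516 with an estimated correlation). Rpl4, Rpl8 and Rps4x rose by 0.39, 0.39 and 0.50, and Rps24 fell by 1.16. Other probe sets measured 0.78 for Rpl4 and −0.50 and −1.06 for Rps24. The ribosomal call was lost without NANCI_shRNA replicate 1 (0.0996) or 2 (0.0765) or NANCI_control replicate 2 (0.0835), with quantile normalization (0.092), with array weights (0.0521) and at or above the median level (0.0915).

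Markers of alveolar type 1 cells, the flat gas-exchange cells, fell after NANCI knockdown in 15 of 24 cases with no rise, or 17 when adjusted over the list alone (median −0.59, adjusted p = 4.79e-09; adjusted p = 0.0798 with an estimated correlation). Basement membrane collagens Col4a3 and Col4a4 measured −2.16 and −1.71, the chloride channel gene Clic5 −1.88 and the sodium channel gene Scnn1g −1.12. Interferon response genes fell in 17 of 35 cases with no rise, or 21 falls and 2 rises when adjusted over the list alone (median −0.38, adjusted p = 1.37e-05; adjusted p = 0.244 with an estimated correlation). The interferon regulators Irf7 and Irf9 measured −1.22 and −1.01, Xaf1 −1.03 and Ifi35 −0.81, where a second Ifi35 probe set measured −0.03 (adjusted p = 0.878). Genes of the unfolded protein response and ATF4, the amino acid and stress response factor, fell in 18 of 32 cases and rose in 3, or 18 and 4 when adjusted over the list alone (median −0.28, adjusted p = 1.37e-05; adjusted p = 0.137 with an estimated correlation). Slc7a11 and Vldlr led these falls, with the pseudokinase gene Trib3 at −1.05 and the ER-stress gene Herpud1 at −0.78. Wnt targets fell in 7 of 20 cases, or 9 with 1 rise when adjusted over the list alone (median −0.21, adjusted p = 0.00825; adjusted p = 0.0872 with an estimated correlation). The feedback inhibitors Rnf43 and Apcdd1 measured −0.58 and −0.40, Bambi −0.47 and cyclin D1 (Ccnd1) −0.34. Epithelial junction and keratin genes fell in 10 of 30 cases and rose in 2, or 12 and 2 when adjusted over the list alone (median −0.12, adjusted p = 0.0309; adjusted p = 0.244 with an estimated correlation). E-cadherin (Cdh1) measured −1.56, with −0.49 on its other probe set (adjusted p = 0.0146), desmoplakin (Dsp) −1.16, occludin (Ocln) −0.48 and F11r −0.37. Without NANCI_control replicate 2 that list had a median of −0.032 and an adjusted p of 0.0885, and the call was lost with array weights (0.0521) and at or above the median level (0.0523).

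The other 17 lists missed the threshold after NANCI knockdown. Among 25 alveolar type 2 and surfactant genes (adjusted p = 0.383), Abca3, the surfactant lipid transporter, Cxcl15 and the protease gene Ctsh measured −1.24, −1.50 and −1.52, 2 genes rose, and the same numbers held adjusted over the list alone. The autophagy regulator Dram1, a p53 target as well, rose by 0.42. Of 33 lung endoderm transcription factors (adjusted p = 0.092), 5 rose and 11 fell, or 5 and 12 adjusted over the list alone. Beside Nkx2-1, Foxp2 and Nfib fell by 1.33 and 1.02, and Etv4, a mediator of FGF signalling, rose by 1.16. Of 33 retinoic acid signalling genes (adjusted p = 0.66), 5 rose and 8 fell, or 7 and 9 adjusted over the list alone. The receptor genes Rara and Rarg and the synthesis gene Aldh1a1 rose by 0.64, 0.49 and 0.65, and the retinal reductase gene Dhrs3 fell by 0.87. Adjusted p-values were 0.092 for mesenchymal and matrix, 0.118 for hypoxia and glycolysis, 0.222 for cholesterol synthesis, 0.259 for Notch, 0.309 for BMP and TGF-beta and 0.309 for proliferation genes. They were 0.346 for FGF and ERK, 0.346 for Hedgehog, 0.346 for endothelial, 0.646 for leukocyte, 0.731 for airway secretory, 0.886 for basal and squamous, 0.886 for fatty acid and phospholipid and 0.934 for ciliated genes. The sign of the median opposed the direction of the test for the airway secretory (0.014), basal (0.023), fatty acid (−0.0031) and leukocyte (−0.0095) lists. With an estimated correlation, camera called 0 of 28 lists after NANCI knockdown, 5 had an unadjusted p under 0.05, and fry called 18.

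With all 6 scrambled arrays as 1 control group, which brings the difference between the sets into the changes and their spread, 16 of 75 named NANCI genes lost their calls (adjusted p from 0.0531 to 0.994). The change was smaller in size in all 16 and shrank by over 1.5 times or turned in 15, as from −2.99 to −1.32 for B4galnt2, from −1.12 to −0.57 for Scnn1g, from −0.78 to −0.37 for Herpud1 and from −0.37 to −0.034 for F11r. They were Aldh1a1, B4galnt2, Ccnd1, Cox6a2, F11r, Gclm, Herpud1, Ifi35, Irf7, Ndufs1, Rarg, Rpl4, Scnn1g, Slc7a11, Trib3 and Xaf1, and the list calls for NRF2 (0.167), unfolded protein response and ATF4 (0.0696, median −0.00096), Wnt (0.167), handling stress (0.076), NF-kB (0.0817) and ribosomal genes (0.0696) ended too. The median of all genes was 0.131 in place of 0.0042, and relative to it the ATF4 median was −0.132 in place of −0.281. Aldh1l2 passed at −1.58 in place of −2.50.

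The term LL34 knockdown stands here for cells given the LL34 shRNA, since the LL34 RNA was not analysed. Against their scrambled arrays, 6766 of 41345 probe sets passed the threshold, 4011 higher and 2755 lower. Of these, 595 changed by at least 1 on the log2 scale. The split between higher and lower depended on scaling: it was 3307 and 3463 after quantile normalization over all arrays and 3062 and 3035 with arrays centred on their medians. Of 22180 named genes, 2166 rose and 2274 fell. The highest rises were in B4galnt2 (3.02, SE 0.129), Cldn1, a tight junction claudin (2.41, SE 0.0952), Cox6a2 (2.27, SE 0.0985), Phf10, a chromatin remodelling subunit (2.26, SE 0.229), and Aldh1l2 (2.11, SE 0.091). The mitochondrial gene Chchd10, the cytokine signalling inhibitor Socs2, Vldlr, Trib3 and the glutathione-degrading enzyme gene Chac1 rose by 1.92, 1.88, 1.74, 1.73 and 1.71. The deepest falls were in Aldh1a1, a retinaldehyde dehydrogenase that makes retinoic acid (−3.04, SE 0.115), Fam180a (−2.60, SE 0.0873), the uroplakin gene Upk3b (−2.46, SE 0.133), Mrgprb3 (−2.40, SE 0.136) and the semaphorin receptor gene Plxnb3 (−2.37, SE 0.129). Thrombospondin 1 (Thbs1), the pantetheinase gene Vnn1, the galectin gene Lgals2, Crip1 and the carbonyl reductase gene Cbr3 measured −2.20, −2.20, −2.12, −2.07 and −1.95. For these 20 genes limma adjusted p-values were at most 0.00058. By the rule that chose them, all shRNA arrays lay on 1 side of all scrambled arrays, as they did in 31% of all probe sets. Second probe sets measured 0.69 for Phf10 (adjusted p = 1.28e-05) and 0.15 for Socs2 (adjusted p = 0.38).

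Genes of the unfolded protein response and ATF4 rose after LL34 knockdown in 22 of 32 cases with 1 fall, or 25 and 1 when adjusted over the list alone (median 0.45, camera adjusted p = 8.42e-18; adjusted p = 0.0213 with an estimated correlation). Vldlr, Trib3 and Chac1 led them, and Mthfd2, a mitochondrial folate enzyme, rose by 1.10. Targets of NRF2 fell in 18 of 22 cases with 1 rise, or 19 and 1 when adjusted over the list alone (median −0.57, adjusted p = 1.71e-13; adjusted p = 0.0225 with an estimated correlation). Cbr3, the quinone reductase gene Nqo1 (−1.76) and the sulfiredoxin gene Srxn1 (−1.25) fell, and Slc7a11 rose by 1.68. The brighter Slc7a11 probe set read exactly the same on all 3 LL34 shRNA arrays, and the other probe set of Slc7a11 measured 0.28 (adjusted p = 0.112). These were the only 2 lists of 28 called with an estimated correlation.

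Lipid synthesis genes fell after LL34 knockdown against the scrambled arrays of their own set. Relative to all genes, those arrays stood above the NANCI scrambled arrays by 0.680 for cholesterol, 0.361 for fatty acid and 0.367 for hypoxia genes. Between the shRNA groups, LL34 minus NANCI, cholesterol genes measured 0.0324 (camera adjusted p = 0.981) and fatty acid genes 0.202 (0.169). For cholesterol synthesis the falls numbered 16 of 19 with no rise, or 17 when adjusted over the list alone (median −0.55, adjusted p = 5.41e-13; adjusted p = 0.161 with an estimated correlation). The sterol synthesis enzymes Cyp51, Hmgcs1 and Sqle and the sterol sensor gene Insig1 measured −1.77, −1.43, −1.21 and −1.11. Of 27 fatty acid and phospholipid genes, 9 fell and 3 rose, or 11 and 4 when adjusted over the list alone (median −0.17, adjusted p = 0.0115; adjusted p = 0.368 with an estimated correlation). Elongases Elovl6 and Elovl5, fatty acid synthase (Fasn) and Acsl5 measured −1.41, −0.70, −0.91 and −0.59. The fatty acid list had a median of −0.11 without LL34_control replicate 2 (adjusted p = 0.0358). Hypoxia and glycolysis genes fell in 11 of 28 cases, or 14 when adjusted over the list alone (median −0.18, adjusted p = 0.000418; adjusted p = 0.161 with an estimated correlation), with the glycolytic genes Aldoc and Tpi1 and the kinase genes Pdk1 and Pfkfb3 at −0.73, −0.69, −0.38 and −0.62. Oxidative phosphorylation genes rose in 12 of 31 cases with no fall, or 15 when adjusted over the list alone (median 0.20, adjusted p = 8.59e-06; adjusted p = 0.226 with an estimated correlation). Uqcrq, Ndufb3, Sdhd and Ndufb5 rose by 0.80, 0.59, 0.44 and 0.36. Ribosomal protein genes rose in 6 of 32 cases with 1 fall, or 7 and 1 when adjusted over the list alone (median 0.11, adjusted p = 0.00694; adjusted p = 0.446 with an estimated correlation). Rpl13, Rpl14, Rpl22 and Rps9 rose by 0.48, 0.41, 0.35 and 0.32. The ribosomal call was lost at or above the median level (0.0569).

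Alveolar type 1 markers fell after LL34 knockdown in 11 of 24 cases with 1 rise, or 12 and 1 when adjusted over the list alone (median −0.23, adjusted p = 1.64e-05; adjusted p = 0.161 with an estimated correlation). Caveolin 1 (Cav1) measured −1.16, Clic3 −0.82, podoplanin (Pdpn) −0.67 and Ahnak −0.51. Interferon response genes fell in 17 of 35 cases with no rise, or 18 when adjusted over the list alone (median −0.28, adjusted p = 7.96e-07; adjusted p = 0.176 with an estimated correlation), among them Ifit1 (−1.30), Cmpk2 (−1.01), Cxcl10 (−0.90) and Gbp3 (−0.60). NF-kB genes fell in 9 of 28 cases, also when adjusted over the list alone (median −0.10, adjusted p = 0.00553; adjusted p = 0.161 with an estimated correlation), with Ccl2, Tnfaip3, Nfkbie and Nfkb2 at −1.12, −0.82, −0.76 and −0.67. Handling stress genes fell in 9 of 25 cases and rose in 2, or 12 and 2 when adjusted over the list alone (median −0.16, adjusted p = 0.00553; adjusted p = 0.226 with an estimated correlation). The phosphatase gene Dusp1, the small chaperone gene Hspb1, Ier3 and Klf6 measured −1.07, −0.82, −0.77 and −0.57. Proliferation genes fell in 15 of 38 cases and rose in 3, or 15 and 4 when adjusted over the list alone (median −0.10, adjusted p = 0.00715; adjusted p = 0.518 with an estimated correlation). The mitotic genes Cdk1 and Cdc20, the replication helicase gene Mcm7 and Rrm2 measured −0.41, −0.39, −0.53 and −0.59.

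Retinoic acid signalling genes fell after LL34 knockdown in 8 of 33 cases with 1 rise, or 9 and 2 when adjusted over the list alone (median −0.13, adjusted p = 0.00969; adjusted p = 0.127 with an estimated correlation). Beside Aldh1a1, the synthesis gene Aldh1a2 measured −1.09, the degrading enzyme gene Cyp26b1 −0.96 and the receptor gene Rarg −0.62. Without LL34_control replicate 3 the retinoic acid list had a median of −0.073 (adjusted p = 0.00484). BMP and TGF-beta targets fell in 8 of 22 cases and rose in 4, likewise when adjusted over the list alone (median −0.11, adjusted p = 0.0262; adjusted p = 0.161 with an estimated correlation), with Smad6, Id1, Tgfb2 and Ccn2 at −0.83, −0.73, −0.63 and −0.53. FGF and ERK feedback genes fell in 8 of 22 cases and rose in 3, the same when adjusted over the list alone (median −0.11, adjusted p = 0.0313; adjusted p = 0.305 with an estimated correlation). The receptor gene Fgfr3, the feedback inhibitor gene Spry1, Phlda1 and Bmp2 measured −0.93, −0.64, −0.84 and −1.53. Without LL34_shRNA replicate 2 the BMP call (0.0568) and the FGF call (0.0724) were lost, the latter also without LL34_control replicate 1 (0.0522), and both were lost at or above the median level (0.0703 each). Mesenchymal and matrix genes fell in 8 of 32 cases with 1 rise, also when adjusted over the list alone (median −0.09, adjusted p = 0.0402; adjusted p = 0.271 with an estimated correlation). Prrx1, the gelatinase gene Mmp2 and the collagen gene Col6a1 measured −1.46, −0.95 and −0.65, and fibronectin (Fn1) rose by 0.38. That call was lost without LL34_shRNA replicate 3 (0.0621) or LL34_control replicate 3 (median −0.036, adjusted p = 0.125), with array weights (0.0866) and at or above the median level (0.126).

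The other 12 lists missed the threshold after LL34 knockdown. Of 25 alveolar type 2 and surfactant genes (adjusted p = 0.685), 3 rose and 2 fell, also when adjusted over the list alone. Surfactant protein B (Sftpb), Etv5 and Cebpa rose by 0.62, 0.57 and 0.56, and Ctsh measured −0.54 (adjusted p = 0.0265). The call for Ctsh was lost without LL34_shRNA replicate 1 (0.0751) or 3 (0.105) or LL34_control replicate 1 (0.0691) or 2 (0.0942). Etv5 (0.055) and Cebpa (0.0527) lost theirs in a fit of the 6 arrays alone, and against all 6 scrambled arrays Sftpb (0.27, adjusted p = 0.354), Etv5 (0.23, 0.436) and Cebpa (0.22, 0.45) all missed. Of 33 lung endoderm transcription factors (adjusted p = 0.609), 5 rose and 8 fell, or 7 and 8 when adjusted over the list alone. The pioneer factor gene Foxa1, Gata6 and Foxp4 measured −1.37, −0.54 and −0.53, and Grhl1 rose by 0.72. Adjusted p-values were 0.116 for airway secretory, 0.155 for endothelial, 0.171 for p53, 0.205 for Notch, 0.239 for basal and squamous, 0.272 for ciliated, 0.438 for leukocyte, 0.438 for epithelial junction, 0.574 for Hedgehog and 0.574 for Wnt genes. Without LL34_control replicate 1, the p53 (0.0396) and airway secretory (0.0463) lists passed.

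Against all 6 scrambled arrays as 1 control group, 34 of 92 named LL34 genes lost their calls (adjusted p from 0.0696 to 0.976). They were Acsl5, Aldh1l2, Aldoc, B4galnt2, Cdk1, Cebpa, Chac1, Chchd10, Cox6a2, Cyp51, Elovl6, Etv5, Fn1, Grhl1, Hmgcs1, Mthfd2, Ndufb3, Ndufb5, Nqo1, Pax9, Pdk1, Phf10, Rpl13, Rpl14, Rps9, Sftpb, Slc7a11, Smad6, Socs2, Sqle, Tpi1, Trib3, Uqcrq and Vldlr. The change was smaller in size in all 34 and shrank by over 1.5 times or turned in 33, as from 3.02 to 1.35 for B4galnt2. Cldn1 (1.59), Rrm2 (−0.91) and Spry1 (−1.01) passed with changes moved by over 1.5 times. The list calls for BMP (0.679), FGF (0.0729), fatty acid (0.935), hypoxia (0.671), handling stress (0.211), proliferation (0.878) and ribosomal genes (0.0576) ended with it, while p53 (0.000878), ciliated (0.0401) and endothelial genes (0.0309) passed. The median of all genes was −0.141 in place of −0.0195, and relative to it the lists for NRF2 (−0.234 in place of −0.555), cholesterol synthesis (−0.274 in place of −0.533) and NF-kB (−0.134 in place of −0.081) passed with medians moved by over 1.5 times. Quantile normalization ended the call for Rpl22 (0.111), and second probe sets of Ccn2 (0.03), Col6a1 (−0.0039), Rrm2 (0.0086), Pdk1 (−0.013), Hspb1 (−0.15), Rps9 (−0.13) and Rpl13 (0.36) missed the threshold after LL34 knockdown.

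**Figure D2:**
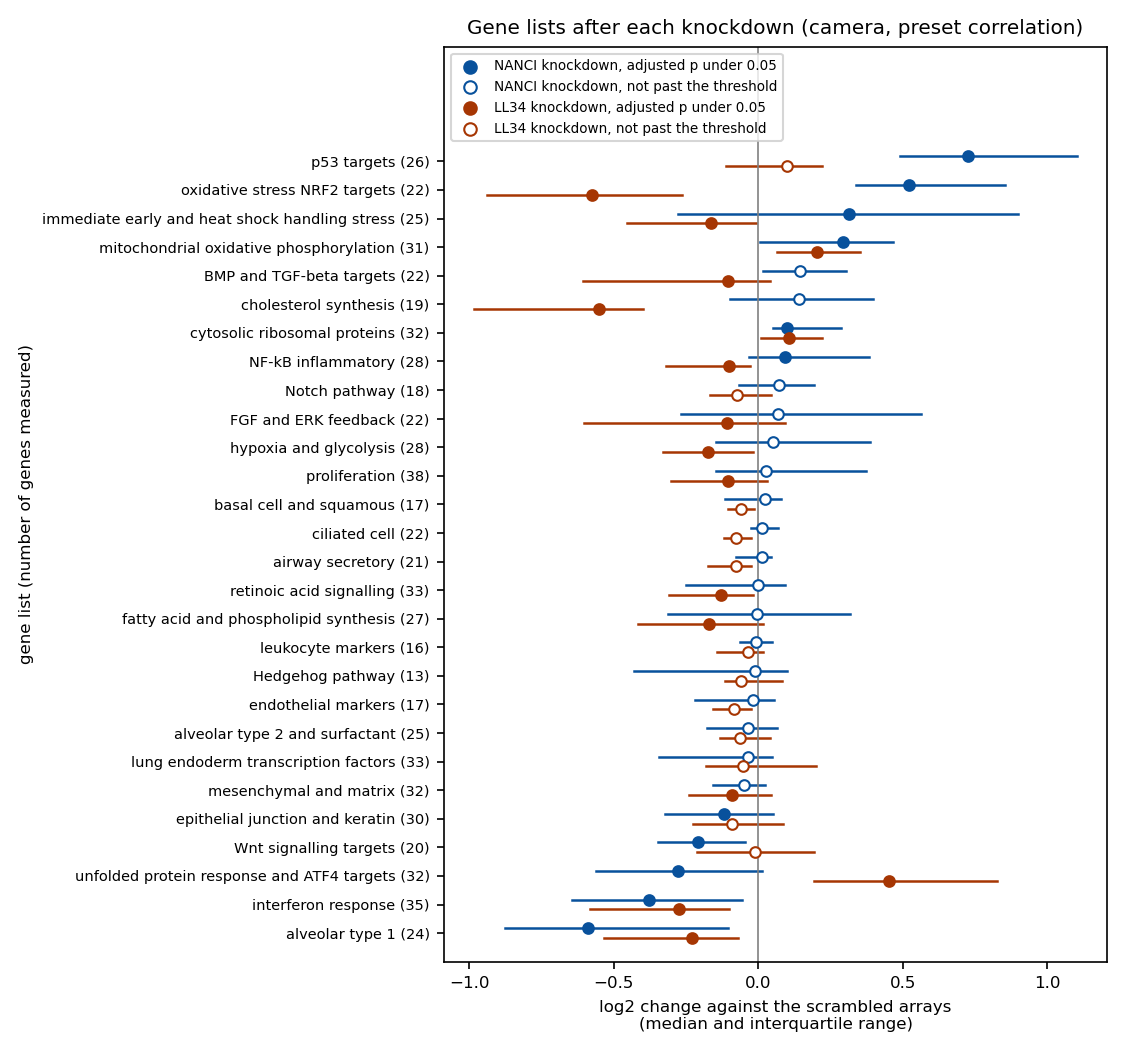
Median log2 change (points) and interquartile range (lines) of the measured members of the 28 gene lists after each knockdown, against the scrambled arrays of the same set, with filled points for an adjusted p under 0.05 from camera at its preset correlation. The unfolded protein response and ATF4 list stood at −0.28 after NANCI knockdown and 0.45 after LL34 knockdown, and the NRF2 list at 0.52 and −0.57.

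The responses to the 2 knockdowns were then compared with each other, for lists by tests added after the data were seen. Each change was taken against the scrambled arrays of its own set, so a difference of changes is not a difference of levels. The change of NRF2 targets was higher for NANCI than for LL34 knockdown by a median of 1.04 (camera adjusted p = 7.08e-16). That of unfolded protein response and ATF4 genes was lower, with a median difference of −0.68 (adjusted p = 4.09e-15). Both calls held with an estimated correlation (adjusted p = 0.019 each). Relative to all genes, the NRF2 list in the LL34 set stood 0.723 above the NANCI set in scrambled arrays, and measured −0.229 between the shRNA groups (adjusted p = 0.0332; adjusted p = 0.723 with an estimated correlation). The ATF4 list measured −0.310 between scrambled groups and 0.595 between shRNA groups (adjusted p = 1.81e-09; adjusted p = 0.14 with an estimated correlation). For NRF2 the difference passed in 21 of 22 members upward and 1 downward, and for ATF4 in 21 of 32 downward and 1 upward, or 23 and 1 when adjusted over the list alone. Of single genes, the difference, NANCI change minus LL34 change, was highest for Aldh1a1 (3.69), Mrgprb3 (3.46), Cbr3 (3.33), Hspa1b (2.98) and the urokinase gene Plau (2.82). It was lowest for B4galnt2 (−6.01), Cox6a2 (−4.82), Aldh1l2 (−4.61), Cldn1 (−4.18) and Slc7a11 (−4.07), with limma adjusted p of at most 6.67e-06 over these 10 genes. This order rests on the direction of the LL34 labels, which no probe set of the LL34 RNA checked here. With all LL34 labels exchanged the difference would be the sum of both changes: −2.40 for Aldh1a1, −1.34 for Mrgprb3, −0.57 for Cbr3, 2.74 for Hspa1b and −0.061 for Plau. It would be 0.030 for B4galnt2, −0.28 for Cox6a2, −0.39 for Aldh1l2, 0.64 for Cldn1 and −0.71 for Slc7a11, with list medians of 0.17 for ATF4 and −0.12 for NRF2.

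Of 41345 probe sets, 7780 differed in response, and 1593 of them by at least 1 on the log2 scale. The NANCI change was higher than the LL34 change in 3569 and lower in 4211. The majority turned with the scaling: 4134 were higher and 4053 lower after quantile normalization, and 3734 and 3650 with arrays centred. The NANCI change was higher than the LL34 change in the lists for cholesterol synthesis (median 0.75, adjusted p = 4.89e-08; adjusted p = 0.277 with an estimated correlation), p53 (0.65, 5.47e-08; adjusted p = 0.227 with an estimated correlation) and handling stress (0.73, 1.63e-05; adjusted p = 0.151 with an estimated correlation). The same held for hypoxia and glycolysis (0.27, 0.000616; adjusted p = 0.227 with an estimated correlation), NF-kB (0.17, 0.00211; adjusted p = 0.151 with an estimated correlation), FGF and ERK (0.22, 0.0103; adjusted p = 0.277 with an estimated correlation) and proliferation genes (0.098, 0.0472; adjusted p = 0.63 with an estimated correlation). Members past the threshold upward and downward numbered 14 and 1 of 19 for cholesterol synthesis (15 and 1 adjusted over the list alone), 16 and 2 of 26 for p53 (18 and 2), 16 and 3 of 25 for handling stress (17 and 4) and 14 and 2 of 28 for hypoxia (16 and 2). They numbered 10 and 1 of 28 for NF-kB (10 and 1), 10 and 1 of 22 for FGF (10 and 3) and 13 and 7 of 38 for proliferation genes (16 and 7), in the same order of counts. Relative to all genes, LL34 minus NANCI shRNA arrays measured 0.0324 for cholesterol synthesis (adjusted p = 0.981), −0.303 for p53 (0.0641), −0.303 for handling stress (0.137), 0.13 for hypoxia (0.856), −0.303 for NF-kB (0.219), −0.282 for FGF (0.175) and 0.119 for proliferation genes (0.856). With all LL34 labels exchanged, the median difference would be −0.66 for cholesterol synthesis, −0.096 for hypoxia, −0.061 for FGF, −0.0125 for proliferation, 0.0071 for NF-kB, 0.335 for handling stress and 0.862 for p53 genes. The proliferation call was lost without NANCI_shRNA replicate 1 (0.0655), NANCI_control replicate 2 (0.13), LL34_shRNA replicate 2 (0.0845), LL34_control replicate 1 (0.116) or 2 (0.0831), with quantile normalization (0.13), with arrays centred (0.0569), with the replicate number as a block (0.0556) and at or above the median level (0.0936). Without NANCI_control replicate 2 its median was 0.065. Among lists that missed, the alveolar type 1 difference (−0.097, adjusted p = 0.0508) passed without NANCI_shRNA replicate 1 (0.0308) or 3 (0.0492), NANCI_control replicate 3 (0.0404), LL34_shRNA replicate 3 (0.0215) or LL34_control replicate 2 (0.0309), and with quantile normalization (0.0384) or arrays centred (0.0357). The Notch difference (0.14, adjusted p = 0.0558) passed without NANCI_shRNA replicate 2 (0.0396), NANCI_control replicate 2 (0.0439) or 3 (0.0399) or with quantile normalization (0.0488), and the fatty acid difference (0.29, adjusted p = 0.125) without LL34_control replicate 3 (0.0455). Interferon response genes did not pass in the difference (0.011, adjusted p = 0.719), which would be −0.637 with the LL34 labels exchanged. Median, mean and test differed in sign for the differences of the alveolar type 2, basal, ribosomal, Hedgehog, interferon and mesenchymal lists.

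**Figure D3:**
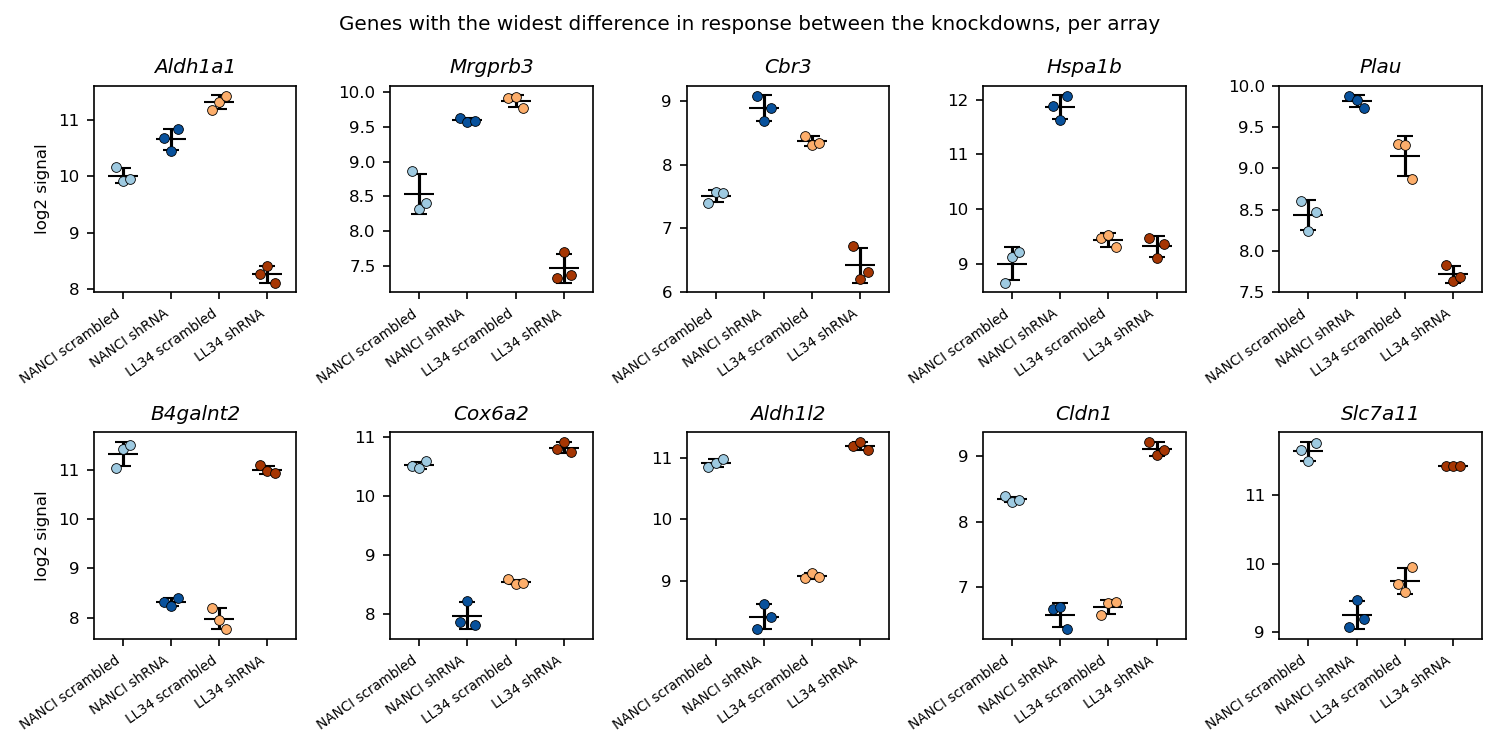
Log2 signal on each of the 12 arrays for the 10 genes with the widest difference in response, with points for arrays and bars for the group mean and SD (3 arrays), each panel on its own scale. B4galnt2, Cox6a2, Aldh1l2, Cldn1 and Slc7a11 were high in the NANCI scrambled and LL34 shRNA groups and low in the other 2 groups, as for Cldn1 at 8.34 and 9.11 against 6.58 and 6.70.

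Genes called in both knockdowns went the same way in 1172 cases and opposite ways in 1225, against 594.6 and 594.1 for independent lists of the same sizes. Rises in both numbered 459 (285.1 for independent lists) and falls in both 713 (309.5). Rises after NANCI with falls after LL34 knockdown numbered 581 (299.3), and the reverse 644 (294.8). Over 22180 genes, the changes correlated at r = −0.0089 and Spearman rho = −0.0012. The correlation is across genes, which are not independent replicates, and the 2 comparisons used separate scrambled arrays. They shared 1 estimate of spread per probe set, which can make calls coincide in any direction. The excess over independent lists, seen in every direction, therefore does not measure a shared response. In the ATF4 list 15 genes fell after NANCI and rose after LL34 knockdown, against 12.4 for independent calls within the list, and in the NRF2 list 15 did the reverse, against 14.7. Interferon genes that fell in both numbered 9, against 8.26 for independent lists, and alveolar type 1 genes 7, against 6.88.

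The 2 groups of scrambled arrays, both labelled as scrambled shRNA, also differed. Over all probe sets the LL34 scrambled group minus the NANCI scrambled group had a median of −0.217, and 22561 of 41345 probe sets passed the threshold, 3533 higher and 19028 lower. That split followed the scaling: it was 7514 and 8684 after quantile normalization and 11653 and 6344 with arrays centred. Igfbp5, an IGF-binding protein, Tecrl and Nqo1 were highest in the LL34 set (2.23, 2.23 and 2.13), and B4galnt2 (−3.33), the antiviral gene Oas1g (−3.03) and Vaultrc5 (−2.84) lowest. Tecrl averaged 4.67 on the NANCI scrambled arrays, under the lower quartiles of 5.56 to 5.59 there, and Oas1g 5.27 on the LL34 scrambled arrays, where the lower quartiles ran from 5.23 to 5.27. Background was not analysed here, so the size and rank of these differences are uncertain. In list tests added after the data were seen, relative to the median of all genes, NRF2 (0.723, camera adjusted p = 7.87e-12), cholesterol synthesis (0.680, 1.77e-14), hypoxia and glycolysis (0.367, 1.64e-06) and fatty acid genes (0.361, 9.8e-06) were higher in the LL34 scrambled arrays. These 4 had adjusted p = 0.0674, 0.177, 0.177 and 0.177 with an estimated correlation. Proliferation (0.318, 4.06e-05), p53 (0.300, 0.000873), handling stress (0.209, 0.0125) and BMP and TGF-beta genes (0.128, 0.0295) were higher too, with adjusted p = 0.408, 0.416, 0.335 and 0.177 with an estimated correlation. Unfolded protein response and ATF4 (−0.310, 0.0018), lung endoderm transcription factor (−0.271, 0.0398) and ciliated genes (−0.121, 0.043) were lower, with adjusted p = 0.294, 0.177 and 0.517 with an estimated correlation. With it camera called 0 of 28 lists, and 6 had an unadjusted p under 0.05. Set, batch and normalization cannot be told apart in this comparison, since each scrambled group lies in 1 set.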

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

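The tests of the scrambled groups alone, of separate normalization, of a response common to targeting shRNAs and of raised interferon genes in scrambled cultures were chosen after the results were seen. The list tests of the difference, the leave-out of both deviating arrays, the values with LL34 labels exchanged and medians relative to all genes against all 6 scrambled arrays were added after the data were seen.

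Changes, each against its own scrambled arrays, differed between the knockdowns for 7780 probe sets and 9 gene lists, by a test of the difference itself. With an estimated correlation 2 of these lists passed, NRF2 and ATF4 (adjusted p = 0.019 each). Relative to all genes, the NRF2 list measured 0.723 between scrambled groups and −0.229 between shRNA groups (LL34 minus NANCI). On that scale, against all 6 scrambled arrays, its medians were 0.0947 in place of 0.517 for NANCI and −0.234 in place of −0.555 for LL34. A difference between the scrambled groups thus stays open as a cause for NRF2. The adjusted p with an estimated correlation was 0.151 for handling stress and NF-kB, 0.227 for p53 and hypoxia, 0.277 for cholesterol synthesis and FGF and 0.63 for proliferation genes. NANCI change minus LL34 change was 3.69 for Aldh1a1, 3.46 for Mrgprb3, 3.33 for Cbr3, 2.98 for Hspa1b and 2.82 for Plau. It was −6.01 for B4galnt2, −4.82 for Cox6a2, −4.61 for Aldh1l2, −4.18 for Cldn1 and −4.07 for Slc7a11. List medians of the difference were 1.04 for NRF2, 0.75 for cholesterol synthesis, 0.73 for handling stress, 0.65 for p53, 0.27 for hypoxia and glycolysis, 0.22 for FGF and ERK, 0.17 for NF-kB, 0.098 for proliferation and −0.68 for unfolded protein response and ATF4 genes. With all LL34 labels exchanged they would be −0.12, −0.66, 0.335, 0.862, −0.096, −0.061, 0.0071, −0.0125 and 0.17 in that order, and the genes would measure −2.40, −1.34, −0.57, 2.74 and −0.061, then 0.030, −0.28, −0.39, 0.64 and −0.71.

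Regrouping arrays bears on chance. Each 3 against 3 comparison has 10 splits, too few for a share under 0.05, and the true split alone (1 of 10) gave its count: 8228 after NANCI and 6766 after LL34 knockdown and 22561 between scrambled groups, against at most 0 in the others. Lists numbered 11 and 16, against at most 8 and 11, again 1 of 10. For the difference, 2 of 100 drawn splits gave at least 7780 probe sets, the labelled split and another with 7949. The latter exchanges all LL34 labels, which tests the sum of the responses. All these splits regroup arrays within a set, so a response in either set makes the labelled split extreme. The share is under 0.05, which bears on arrays without any response. It cannot say whether the responses of the 2 sets differed. Of these splits 13 of 100 gave at least 9 lists (highest 14), so for the lists chance was not excluded. A correlation at least as far from 0 as −0.0089 came from 99 of 100 (highest 0.268). Almost any split reaches a value this near 0, so the splits cannot bear on the correlation.

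Genes of the unfolded protein response and ATF4 fell after NANCI knockdown (adjusted p = 0.137 with an estimated correlation) and rose after LL34 knockdown (adjusted p = 0.0213 with an estimated correlation). A difference between scrambled cultures alone, with the sets otherwise alike, would leave both shRNA groups alike. The list was higher in the LL34 than in the NANCI shRNA arrays by 0.595 relative to all genes (camera adjusted p = 1.81e-09; adjusted p = 0.14 with an estimated correlation), where the scrambled groups differed by −0.310. That contrast runs between sets, where set, batch and normalization cannot be told apart, and was chosen after the opposite changes were seen. It cannot exclude the scrambled cultures as the cause. For separate normalization, the median difference was −0.663 after quantile normalization over all arrays (camera adjusted p = 2.38e-15, and from 1.22e-16 to 0.019 over 22 alternatives). Each change was already taken within a set, and this step cannot undo a separate summary of probe sets in each set. It therefore does not decide on that cause. Signal level was argued against by 0 of 10000 random lists matched on signal as low as −0.684. What stays open is a difference between scrambled cultures, separate normalization, culture state, such as amino acid supply at collection, an exchange of all LL34 labels, which may not be ruled out because the LL34 RNA was not analysed here, and an effect of the knockdowns. Against all 6 scrambled arrays the NANCI median was −0.00096 in place of −0.277 (adjusted p = 0.0696), or −0.132 in place of −0.281 relative to all genes, so the call for the NANCI fall rests on the scrambled arrays of its own set.

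Targets of p53 rose after NANCI knockdown with a median of 0.724 (adjusted p = 0.0872 with an estimated correlation), in a line whose large T antigen binds p53. Against a response common to any targeting shRNA as the whole cause stood the median of 0.101 after LL34 knockdown, with the difference at a camera adjusted p of 5.47e-08 (0.227 with an estimated correlation, and from 6.17e-09 to 0.227 over 22 alternatives). Other values went the other way. Relative to all genes, the LL34 scrambled arrays stood 0.300 above the NANCI scrambled arrays (adjusted p = 0.000873, 0.416 with an estimated correlation), and the shRNA groups measured −0.303 (LL34 minus NANCI, adjusted p = 0.0641). Against all 6 scrambled arrays the LL34 median was 0.164 (adjusted p = 0.000878), or 0.304 relative to all genes against 0.579 for NANCI. A common response was thus not excluded. The deviating scrambled array was argued against by a median of 0.790 without NANCI_control replicate 2 (adjusted p = 1.43e-13, and from 4.8e-15 to 0.0872 over 24 alternatives), and signal level by 0 of 10000 random lists. An effect of the NANCI RNA, an effect of this shRNA on other transcripts, a response common to targeting shRNAs, or stress in these cultures may account for the rise after NANCI knockdown, since each target had 1 shRNA group.

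Interferon response genes fell after both knockdowns (medians −0.379 and −0.276), and both calls were lost with an estimated correlation (adjusted p = 0.244 and 0.176). The deviating arrays were argued against by medians of −0.432 and −0.358 without NANCI_control replicate 2 and LL34_control replicate 3 (adjusted p = 6.34e-07 and 3.66e-09; from 6.34e-07 to 0.244 and from 3.66e-09 to 0.176 over 24 alternatives each), and signal level by 0 of 10000 random lists in either knockdown. Whether scrambled virus raised these genes stays open: the scrambled groups differed by −0.260 relative to all genes (adjusted p = 0.0949), and uninfected cells were not analysed here. Against all 6 scrambled arrays the medians were −0.187 and −0.506 (adjusted p = 0.00436 and 1.71e-06), or −0.318 and −0.365 relative to all genes in place of −0.383 and −0.256. An effect of the knockdowns stays open too, as does an exchange of all LL34 labels, with which the LL34 median would be 0.276 and the pattern in both would end.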

How the results depend on the processing

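Leaving out both deviating scrambled arrays, and all settings of the list tests of the difference, were chosen after the data were seen. Counts of called probe sets stayed within 1.5 times their values in all settings but these: 622 for NANCI, 595 for LL34, 1593 for the difference and 1003 for the scrambled groups at a change of at least 1 on the log2 scale, by construction; 3883 for LL34 and 4905 for the difference at a threshold of 0.01; 10994 for the scrambled groups among probe sets at or above the median level, where fewer were tested; and 4309 for LL34 with all 6 scrambled arrays as 1 control group, which brings the difference between sets into the changes and their spread. Called lists numbered 0 for NANCI (5 at an unadjusted p under 0.05), 2 for LL34 and 2 for the difference with an estimated correlation, 18 for NANCI and 17 for the difference with fry, which does not compare a list with other genes, and 6 for NANCI with the scrambled arrays as 1 group. The correlation of responses was 0.00374 with array weights, −0.0629 with the scrambled arrays as 1 group, which then shares controls, and 0.027 without both deviating arrays. With the scrambled arrays as 1 group the cholesterol list turned downward after NANCI knockdown (camera adjusted p = 0.0236), Aldh1a1 measured −0.0036 and Trib3 0.066. These shifts follow from the scrambled groups, whose mean then serves as the control. Aldh1a1 averaged 10.005 on the NANCI and 11.305 on the LL34 scrambled arrays, and Trib3 10.228 and 7.99. The cholesterol list stood 0.680 higher in the LL34 scrambled arrays, relative to all genes. Why the scrambled groups differed was not tested. Over the 12 arrays left out in turn, counts ran from 6699 to 9551 for NANCI, 4704 to 6670 for LL34, 6519 to 8111 for the difference and 19420 to 24051 for the scrambled groups. Lists ran from 9 to 11, 14 to 17 and 8 to 11, and the correlation from −0.0258 to 0.016. The replicate block gave 6906, 5257, 6320 and 21041 probe sets, 11, 16 and 8 lists, and r = −0.0089, with no sign that numbers pair arrays. Same-numbered arrays of a set deviated with correlations of −0.00902, 0.0123 and −0.0568 (NANCI) and 0.0451, −0.0505 and −0.125 (LL34), and 1 of 6 correlated best with its own number. Under the block, Nkx2-1 after LL34 knockdown (adjusted p = 0.0664) and the proliferation difference (0.0556) missed the threshold. Without both deviating arrays 9359, 6617, 8260 and 22451 probe sets were called. Over all named genes and settings, 4104 values kept their side of the threshold, 66 lost the call and 1 gained it. Another 2, Aldh1a1 and Trib3 above, turned sign and lost the call. Called values among the 4104 kept their direction, while uncalled ones could turn, as for Mbip after LL34 knockdown (from −0.0182 to 0.0893). Background signal was not analysed here.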

Other observations

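The genes shared by both knockdowns and the overlap within lists were examined after the results were seen, and hold if the LL34 labels run as given, which no probe set of the LL34 RNA checked here.

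Among 697 genes with a full name that fell in both, 25 fell by at least 1 on the log2 scale in each, while none of 436 that rose in both reached that size. Ranked by the smaller of the 2 changes, Prrx1, a mesenchymal homeobox gene, came first (−1.57 after NANCI and −1.46 after LL34 knockdown), then Edn1, the endothelin 1 gene (−1.50 and −1.45), Orm1, an acute-phase protein (−1.40 and −1.73), Rhou, a small GTPase (−1.64 and −1.37), the uroplakin gene Upk1b (−1.35 and −1.63) and Ildr2 (−1.29 and −1.27). Uspl1 (0.98 and 1.05), the zinc finger genes Zbtb39 (1.19 and 0.94) and Zfp568 (0.93 and 0.90), Fam126b (0.87 and 0.79), Dicer1, the microRNA-processing RNase (0.81 and 0.78), and Mcfd2 (0.75 and 0.79) led the rises. The largest limma adjusted p among these 12 genes was 0.00401. With all LL34 labels exchanged every LL34 change here would turn its sign, 621 other genes would fall in both, 19 of them by at least 1, and 568 would rise in both, 7 of them by at least 1.

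Mesenchymal and matrix genes fell in both knockdowns in 5 of 32 cases, against 1.5 for independent calls, a ratio of 3.33. Lung endoderm transcription factors did so in 6 of 33 cases, against 2.67, a ratio of 2.25, and endothelial markers in 2 of 17, against 0.235, a ratio of 8.5. These 3 had the lowest of 28 p-values by Fisher's exact test within each list (two-sided, adjusted p = 0.0423, 0.0767 and 0.0767), and the endothelial ratio rests on 2 genes. The test takes the calls of both knockdowns as independent, though they shared 1 estimate of spread per probe set. Its p-values therefore do not show a shared response. Wnt targets had a ratio of 2.29 (4 genes), and ciliated (11), alveolar type 2 (4.17), Hedgehog (3.25) and Notch genes (2.25) had ratios that rest on 1 gene each. With all LL34 labels exchanged, falls in both for the first 3 lists would number 1 of 32 (0.188 for independent calls), 1 of 33 (1.67) and 0 of 17 (0). Over all genes the ratio for falls in both was 2.3 (713 against 309.5), or 2.18 with the labels exchanged (644 against 294.8), and whether a list's ratio differed from it was not tested.

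The scrambled arrays NANCI_control replicate 2 and LL34_control replicate 3, of different sets, deviated from their groups alike: over probe sets their deviations correlated at 0.561, where the next pair of arrays from different groups reached 0.319. Zfp119a (−1.0 and −0.95), Chp1 (−0.69 and −1.03), the interferon-inducible gene Ifi204 (−0.66 and −0.56), Zfp972 (−0.54 and −0.54), Lgals2 (−0.65 and −0.51) and Zfp97 (−0.50 and −1.33) lay furthest below their groups on both. Furthest above were Olfr1158 (0.40 and 0.57), Vmn1r119 (0.39 and 0.42), Mtarc1 (0.41 and 0.37), Upk2 (0.36 and 0.37), Tmem45b (0.35 and 0.39) and Plpp4 (0.34 and 0.37).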
